A study of Mus musculus with 4 samples.

How the data were processed

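The series holds 4 RNA-seq libraries of mouse THY1-positive spermatogonia from postnatal day 4, grouped by the genotype in the labels as 2 control and 2 mutant libraries. Per the labels' protocols, cells were enriched from testis with antibody-conjugated magnetic beads, RNA was extracted with Trizol and libraries were made by standard Illumina procedures. TopHat2 2.0.11 and the GRCm38 build are named in the submitters' processing notes. The counting program and the gene annotation are not given in the sources used here. Per the file headers, the deposited values are RPKM, with 1 column for both control libraries together and 1 for both mutant libraries. How the libraries were combined is not given in the sources used here. The labels do not say whether the libraries of a genotype came from separate animals.

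The combined columns changed the planned tests. Before the data were examined, the plan was a moderated linear model (limma) on log2 values of the 4 libraries, gene set tests on that fit, and a rule for named genes that used adjusted p-values. None of these can be run on 1 value per genotype. A 2-fold difference without a p-value, which the plan held as a second way of counting, was used in their place, without its condition that replicates must not overlap. Every gene was given as log2((mutant RPKM + 1) / (control RPKM + 1)), a scale that understates the difference of genes with low values. A gene entered the comparison with an RPKM of 1 or more in either genotype. Of 43998 entries in the table, 13903 were at 0 in both genotypes and 17278 passed this filter. Of the latter, 774 pooled several overlapping gene symbols in 1 value and were left out of the counts and lists, which left 16504. Where a symbol occurred more than once, the entry with the highest mean was used. Across these genes Pearson's r between the log2 values of the genotypes was 0.887, computed across genes, which are not independent replicates.

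Starts in the table count from 0, and 1 was added to each. After that, 21667 of 39566 symbols found once in GENCODE M21 had exactly the same start and end. GENCODE M21 on GRCm38 was used for gene biotype, transcript length and GC content only, with 15488 of the 16504 genes matched by symbol. Counts of protein-coding genes cover matched genes only, while the protein-coding ranking also took named genes without a match.

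Depth was read from the low values. For 2180 control and 2248 mutant genes with 1 annotated transcript of at least 1000 nt, RPKM multiplied by transcript length less a fixed offset (200 nt for control, 210 nt for mutant) was set against multiples of 1 read. Of 884 low control values up to 10 reads, 90.5% lay within 0.1 of a whole read, as did 95.3% of 900 mutant values. The steps of 17.85 and 17.45 RPKM × nt per read correspond to 56.0 M and 57.3 M reads, if no further scaling factor entered the values. An RPKM of 1 in a 2-kb transcript then stands for about 101 control and 103 mutant reads, and a floor of 3 reads for 0.0298 and 0.0292 RPKM. Whole reads per library could not be had from combined values. The columns sum to 1005894 RPKM in control and 901449 RPKM in mutant. The small RNA genes Rmrp and Rpph1 alone hold 12.2% and 12.3% of these sums, small noncoding genes 25.3% and 25.8%, and protein-coding genes 45.5% and 45.2%. The median gene in the comparison stood at 9.65 RPKM in control and 9.36 RPKM in mutant, and the median log2 difference was 0.005.

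The 27 gene lists written in advance were retinoid receptors, retinoic acid responsive genes, retinoid metabolism and transport, undifferentiated spermatogonia, differentiating spermatogonia, meiosis, germ cell identity and piRNA, late spermatocyte and spermatid, replication-dependent core histones, linker histones, replication-independent histone variants, histone mRNA expression and processing factors, S phase and DNA replication, G2 and M phase, cyclins and CDK inhibitors, p53 targets, Sertoli cells, Leydig cells, peritubular myoid cells, interstitial fibroblasts, endothelial cells, macrophages, lymphocytes, erythroid cells, immediate early and dissociation stress, mitochondrially encoded and cytosolic ribosomal proteins. Another 5 were added after the values were seen, for mast cells, spermatogonial stem cell associated genes, early progenitor associated genes, DNA methylation and chromatin of prospermatogonia, and Y-linked genes. Each list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these values. A bootstrap of 10000 draws over the genes of a list gave its 95% interval, which covers the choice of genes and not animals or libraries. Further random lists, of protein-coding genes, were matched on expression in 5 bins together with transcript length or GC content in 20 bins. No list was matched on both length and GC content. Such trends were present: the shortest decile of protein-coding genes had a median log2 difference of -0.27 and the longest 0.15, and the lowest GC decile had 0.11 and the highest -0.20.

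The rule for named genes had 3 parts. The first took the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those meeting the 2-fold rule with an RPKM of at least 5 in the higher genotype, leaving out gene models without a given name. The second took the 6 retinoid receptors with Stra8, Kit, Gfra1, Zbtb16, Thy1 and Ddx4. The third took up to 4 members of each list past the 2-fold rule by size, or otherwise the 2 with the highest expression. The conditions on p and on replicates in the written rule could not be applied. Other named genes, among them the protein-coding ranking, all members past the rule in the spermatogonial lists, Sohlh1, Sohlh2, Dazl, Tdrd5, Dppa3, Meiob and Hist1h2ba, were chosen after their values were seen.

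Alternatives were pseudocounts of 0.1 and 0.5, no filter, an RPKM of 5 or more, quantile normalization and median ratio rescaling. Added after seeing the data were rescaling to a germ cell identity median of 0, protein-coding genes alone, inclusion of entries with several symbols, and removal of the length and GC trend in 10 bins each.

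The calculations were tested on 16504 simulated genes for mutant against control. Every simulated gene had the same noise, with a spread taken from the real differences between mutant and control and not from replicates. Control values under 0.5 RPKM were raised to 0.5. The 2-fold rule recovered 28.4% of 67 genes made with a 2-fold change, 85.1% of 67 with 3-fold and 97.0% of 66 with 4-fold, and took 2.50% of 16304 unchanged genes. These shares are therefore no error rate for the real genes. Of 200 unshifted lists of 30 genes 4% lay outside the central 95% of random lists, and of 200 lists lowered by 0.5 on the log2 scale 100% did. The simulated lists were drawn at random from genes with independent noise, so a small share of unshifted lists followed from the design. It is no error rate for real lists, whose genes can vary together. A read step made as 18 was recovered as 18.25. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.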

Results

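RNA of spermatogonia from 4-day-old C57BL/6 mice was sequenced in 4 libraries, 2 from control animals and 2 from animals in which retinoic acid signalling was impaired in the germ cells. Retinoic acid is the vitamin A metabolite that starts spermatogonial differentiation. The cells had been taken from the testis with magnetic beads against THY1 (CD90.2), a surface protein used to enrich undifferentiated spermatogonia. The deposited table holds 1 combined RPKM value per gene for each genotype (reads scaled to transcript length and to the depth of sequencing), made from both libraries. No difference below could therefore be set against a spread between replicates, and no SD, n or p-value is given. The low values stepped in whole reads. If no further scaling factor entered the values, the steps placed the depth behind the control values near 56.0 M reads and that behind the mutant values near 57.3 M reads. At this depth an RPKM of 5 in a transcript of 1 kb stood for about 224 control reads (95% Poisson interval 196 to 255) and about 226 mutant reads (197 to 257), which covers counting error only.

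The comparison of mutant with control asked which transcripts differ in early spermatogonia when their retinoic acid signalling is impaired. Stra8, a retinoic acid target needed for meiotic entry, was 5.25-fold lower in the mutant value, at 45.2 RPKM in control and 8.60 RPKM in mutant. Kit, the receptor tyrosine kinase that marks differentiating spermatogonia, was 2.83-fold lower (27.3 and 9.65 RPKM). Genes of retinoic acid response and core histone genes had lower mutant values as groups, and genes of germ cell identity had higher ones. Markers of macrophages, mast cells, Leydig cells and Sertoli cells were lower in the mutant as well.

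Of 16504 genes with an RPKM of 1 or more in either genotype, 729 had a mutant value at least 2-fold above control and 718 a value at least 2-fold below it, on the log2(RPKM + 1) scale. This scale understates the difference of genes with low values, and the 2-fold rule for single genes and list members refers to it throughout. Among the 12205 protein-coding genes in that set, 162 were higher and 495 lower by this 2-fold rule. Most of the 729 higher genes were thus entries not matched as protein-coding, while most of the 718 lower ones were protein-coding. The numbers describe these combined values and carry no error rate. With a pseudocount of 0.1 they were 1424 higher and 1111 lower.

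The retinoid receptors were read first, because the labels do not name the modified gene. Rara, the gene of retinoic acid receptor alpha, was at 20.6 RPKM in control and 19.4 RPKM in mutant (log2 difference -0.08). Rarg, on chromosome 15 from 102234938 to 102257517 in GRCm38, was 2.65-fold higher in the mutant (5.22 and 13.8 RPKM, log2 difference 1.25). Rarb was near the limit of use in both values (0.554 and 0.309 RPKM). Rxra was at 36.2 and 32.6 RPKM, Rxrg at 1.81 and 1.32 RPKM, and Rxrb was 1.02-fold lower in the mutant at 18.7 RPKM. Of the 5 receptors with an RPKM of 1 or more, Rarg met the 2-fold rule and the other 4 lay slightly below 0, with a list median of -0.08 at percentile 35.8 of random lists matched on expression. Removing the trend with transcript length and GC content turned this median to 0.05, and Rarg was no longer past 2-fold after rescaling to a median of 0 in the germ cell identity list. A gene-level RPKM over a whole transcript does not show whether an exon was deleted or a modified receptor was expressed.

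All 9 measured retinoic acid responsive genes had lower mutant values, and 4 of them by 2-fold or more. The number past 2-fold was 2 with the length and GC trend removed, 6 with a pseudocount of 0.1 and 7 after rescaling to the germ cell list. Their median log2 difference was -0.83 (95% bootstrap interval over genes -1.40 to -0.33), at percentile 0.01 of the matched random lists. Besides Stra8 (chromosome 6, 34920163 to 34939344), these were Dhrs3, a retinal reductase induced by retinoic acid, at 57.6 and 21.2 RPKM, and Cyp26b1 and Cyp26a1, which break down retinoic acid. Cyp26b1 was at 8.02 RPKM in control and 3.41 RPKM in mutant, and Cyp26a1 at 1.84 and 0.409 RPKM. Retinoid metabolism and transport genes were lower for 15 of 17 members, 6 of them by 2-fold or more, with a median of -0.79 that lay below all 10000 random lists. Adh1, an alcohol dehydrogenase acting on retinol, was at 88.7 and 21.7 RPKM. Fabp5, a fatty acid and retinoic acid binding protein, was at 49.2 and 15.9 RPKM, and Aldh1a1, which makes retinoic acid from retinal, at 94.9 and 39.1 RPKM. Several genes of these lists are also expressed in testicular somatic cells, whose markers were lower in the mutant by similar amounts.

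Genes of undifferentiated spermatogonia did not move as a block. Of 40 measured members, 5 were higher and 3 lower by the 2-fold rule, 19 lay above 0 and 21 below, and the median of -0.04 lay at percentile 34.8. The higher members were Neurog3, Sox3, Upp1, Piwil4 and Zbtb16. Neurog3, a transcription factor of progenitor spermatogonia, was at 1.40 RPKM in control and 6.94 RPKM in mutant, and Sox3, also of progenitors, at 3.47 and 11.3 RPKM. Upp1, a uridine phosphorylase, was at 7.07 and 20.8 RPKM, and Piwil4, a PIWI protein of fetal and neonatal germ cells, at 5.94 and 14.7 RPKM. Zbtb16, which encodes the self-renewal factor PLZF (chromosome 9, 48654311 to 48835945), was 2.20-fold higher at 24.4 and 53.7 RPKM. The lower members were Gfra1, the GDNF co-receptor of stem spermatogonia (chromosome 19, 58204139 to 58455909), at 35.9 and 14.2 RPKM, Sall4 at 72.3 and 30.3 RPKM, and Pou5f1 at 40.4 and 17.1 RPKM. Thy1, the gene of the protein used for selection, was at 7.11 RPKM in control and 8.61 RPKM in mutant, and its log2 difference of 0.24 became negative when values were rescaled to the germ cell list. The median of the undifferentiated list was 0.14 when an RPKM of 5 was required and 0.03 with the length and GC trend removed. After rescaling to the germ cell list 2 members were higher and 12 lower by the 2-fold rule. Lower members past 2-fold were 5 with a pseudocount of 0.1 or 0.5 and 4 with quantile normalization.

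**Figure D1:**
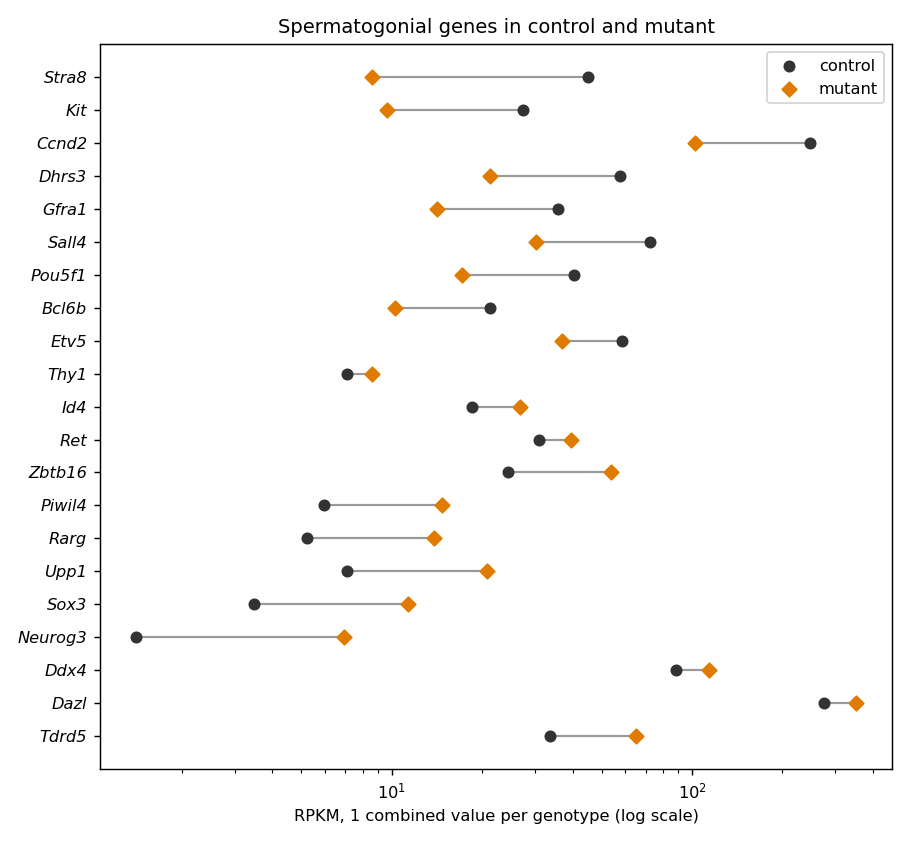
RPKM on a log scale, with 1 combined value per genotype, for spermatogonial genes; circles are control, diamonds are mutant, and a line joins the values of a gene. Stra8 has the widest gap among the genes lower in the mutant (45.2 and 8.60 RPKM) and Neurog3 among those higher in it (1.40 and 6.94 RPKM), and Gfra1 and Zbtb16 lie apart in opposite directions.

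Genes of differentiating spermatogonia split. Of 20 measured members, 5 were at least 2-fold lower and none 2-fold higher, yet 13 lay above 0, so the median was 0.32 (percentile 99.8) while the mean was -0.07. The 5 were Stra8, Kit (chromosome 5, 75574916 to 75656722), Cyp26a1, the D-type cyclin gene Ccnd2 at 247 and 102 RPKM, and Ddit4l, an inhibitor of mTOR signalling, at 9.17 and 3.23 RPKM. The transcription factor genes Sohlh1 and Sohlh2, needed for early differentiation, were instead higher in the mutant, at 37.2 and 60.6 RPKM and at 30.8 and 50.5 RPKM, without reaching 2-fold. The list median turned to -0.14 when values were rescaled to the germ cell list. With the length and GC trend removed, 2 of 19 members were 2-fold higher and 4 were 2-fold lower. Mast cell genes, which come from cells that also carry Kit, were lower in the mutant with a median of -1.15, or -2.76 with a pseudocount of 0.1.

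Germ cell identity and piRNA genes were higher in the mutant for 23 of 26 members, with a median of 0.46 (bootstrap interval 0.33 to 0.64) above all 10000 random lists. On the RPKM + 1 scale none was 2-fold higher and Sall4 alone was 2-fold lower; Dppa3, at 1.30 and 3.50 RPKM, passed 2-fold with the smaller pseudocounts. Markers of macrophages (median -1.30), Leydig cells (-0.93), Sertoli cells (-0.83) and interstitial fibroblasts (-0.67) were lower in the same mutant values. Ddx4, the germ cell RNA helicase VASA, was at 88.6 and 114 RPKM, Dazl at 274 and 353 RPKM, and the piRNA pathway gene Tdrd5 at 33.6 and 65.0 RPKM. Meiosis genes lay above 0 for 23 of 33 members, with a median of 0.16 at percentile 96.0, and none met the 2-fold rule. The percentile was 99.8 for lists matched on length and 94.6 for lists matched on GC content. Meiob, at 0.428 and 1.40 RPKM, passed 2-fold with the smaller pseudocounts. The cohesin gene Stag3 was at 98.1 and 141 RPKM and Tex15, a factor of meiotic recombination and silencing, at 69.2 and 120 RPKM. Of 6 measured late spermatocyte and spermatid genes, Adam3 was 2-fold lower (2.34 and 0.542 RPKM), and the list had a median of 0.06 at percentile 50.2 and a mean of -0.13. Rescaling to the germ cell list brought that list to 0 by construction and turned the meiosis median to -0.30 and the spermatid median to -0.40.

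Replication-dependent core histone genes, which supply histones during S phase, were lower in the mutant for 55 of 56 measured members. Their median log2 difference was -0.66 (bootstrap interval -0.79 to -0.61), below all 10000 random lists matched on expression, and 6 members met the 2-fold rule. The number past the rule was 1 with the length and GC trend removed, 3 with quantile normalization, 9 with a pseudocount of 0.1 and 40 after rescaling to the germ cell list. Hist1h2bh was at 120 RPKM in control and 47.8 RPKM in mutant, Hist1h4i at 51.5 and 22.8 RPKM, Hist1h2ae at 66.3 and 30.4 RPKM, and Hist1h3i at 166 and 81.6 RPKM, all from chromosome 13. The summed RPKM of 15 H2A genes was 1920 in control and 1316 in mutant, a ratio of 0.686. The ratio was 0.627 for 18 H2B genes, 0.635 for 10 H3 genes and 0.714 for 13 H4 genes. Hist1h2ba, which encodes a testis-specific H2B, was the 1 member above 0 (201 and 222 RPKM), and it lay below 0 when values were rescaled to the germ cell list. The list was taken from what is known of the study of these samples, so its direction is not independent evidence, and near-identical copies can share reads, which leaves single histone genes uncertain. With the length and GC trend removed the median was -0.32, with 51 of 54 members still below 0. Markers of interstitial fibroblasts (median -0.67) and Sertoli cells (-0.83) were lower in the same values, while endothelial genes had a median of 0.06.

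**Figure D2:**
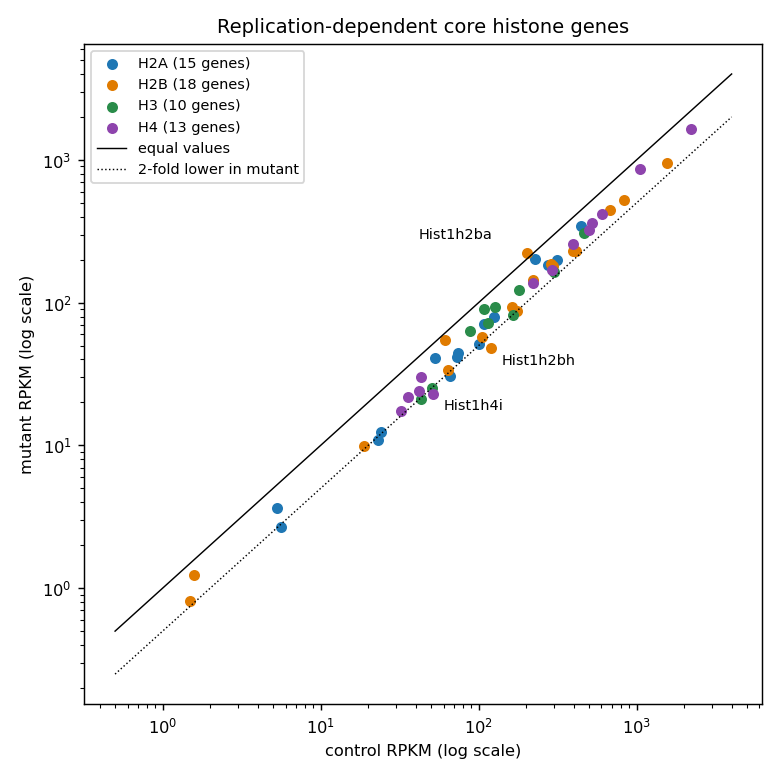
Control RPKM (horizontal, log scale) against mutant RPKM (vertical, log scale) for 56 replication-dependent core histone genes, coloured by family; the solid line marks equal values and the dotted line a 2-fold lower mutant value. Of the 56 points 55 lie under the solid line, and Hist1h2ba lies just above it, a position that reverses when values are rescaled to the germ cell list.

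Other histone and cell cycle lists had smaller differences. Of 7 linker histone genes, Hist1h1b was 2-fold lower (226 and 101 RPKM) and the median was -0.50 at percentile 2.73. With the length and GC trend removed Hist1h1b was no longer past the rule, at -0.78. The linker list median was then -0.16 at percentile 24.2, and 1 member was 2-fold higher. All 9 replication-independent histone variants lay below 0, with a median of -0.32 at percentile 15.2, and none met the 2-fold rule; H3f3b was at 709 and 654 RPKM and H2afz at 698 and 497 RPKM. Of the 18 histone mRNA expression and processing factors none met the rule, and their median was -0.07 at percentile 37.7. Slbp, which binds the histone mRNA stem-loop, was at 139 and 119 RPKM, and the histone chaperone gene Nasp at 164 and 172 RPKM, a difference of 0.07 that reversed when values were rescaled to the germ cell list. S phase and DNA replication genes lay below 0 for 35 of 37 members without meeting the 2-fold rule, and their median of -0.34 was at percentile 0.19. Pcna, the sliding clamp of DNA polymerase, was at 164 and 109 RPKM. The 33 genes of the G2 and M phase list had a median of -0.14 at percentile 12.9, with Cdk1 at 139 and 87.9 RPKM and Ccnb1 at 115 and 97.7 RPKM. Ccnd2 was the 1 of 20 cyclins and CDK inhibitors to meet the rule, with a list median of -0.30 at percentile 2.70, or 1.8 when an RPKM of 5 was required. Of 19 p53 targets, Pmaip1, which encodes the apoptosis promoter NOXA, was 2.67-fold higher at 58.8 RPKM, Ddit4l and Gdf15 (4.73 and 1.39 RPKM) were lower, and the median was -0.42 at percentile 0.25.

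Markers of other testicular cells differed by cell type. Macrophage genes were lower for all 15 members, 13 of them by 2-fold or more, with a median of -1.30, and examples were the lysozyme gene Lyz2 at 1339 and 428 RPKM, Cd68 at 249 and 84.0 RPKM, Tyrobp at 677 and 230 RPKM and the complement gene C1qa at 646 and 231 RPKM. All 11 Leydig cell genes were lower, 5 by 2-fold or more, with a median of -0.93, and the steroidogenic genes Cyp17a1 and Hsd3b1 were at 148 and 42.7 RPKM and at 266 and 94.7 RPKM. Sertoli cell genes were lower for 24 of 26 members, 6 by 2-fold or more, with a median of -0.83 and Clu at 188 and 81.8 RPKM. Interstitial fibroblast genes had a median of -0.67, with 17 of 17 lower and 4 past the 2-fold rule, among them Igf1 at 59.7 and 28.1 RPKM. These lists had medians below all 10000 random lists, as did the 6 erythroid genes (median -1.96, 4 past the rule, Hbb-bs at 224 and 33.8 RPKM). With the length and GC trend removed, 11 macrophage, 4 Leydig, 1 fibroblast and 0 Sertoli genes were past the 2-fold rule, and after rescaling to the germ cell list 14, 9, 10 and 21 were. Without the filter on low values the erythroid median was -0.30 over 9 genes, at percentile 1.3. Of 9 peritubular myoid genes, Acta2 met the rule at 66.1 RPKM in control and a log2 difference of -1.37, and the median was -0.63 at percentile 0.48.

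Endothelial and lymphocyte genes did not share this direction. The 12 endothelial genes split evenly about 0, with none past the 2-fold rule, a median of 0.06 at percentile 50.6 and a mean of -0.01. Cdh5 was at 8.62 and 7.38 RPKM and Pecam1 at 6.92 and 6.17 RPKM. The 10 lymphocyte genes had a median of 0.05 at percentile 54.5 and a mean of -0.19, with Cd79b (12.2 and 4.32 RPKM) and Cd4 (21.7 and 9.98 RPKM) 2-fold lower. Both medians were negative after quantile normalization, after rescaling to the germ cell list and when an RPKM of 5 was required, where the 4 lymphocyte genes left had a median of -0.65 at percentile 1.5. With the length and GC trend removed no lymphocyte gene was past the 2-fold rule. Of 20 immediate early and dissociation stress genes, Ier2 (59.0 and 22.2 RPKM) and Ier3 (47.9 and 18.3 RPKM) were 2-fold lower, with a list median of -0.32 at percentile 0.80. That position was inside the central 95% of lists matched on GC content (8.95) and with the length and GC trend removed (3.5). The 62 cytosolic ribosomal protein genes were centred at -0.01, with none past the rule, at percentile 99.95 because matched random lists lay lower. Rps15a was at 3198 and 3854 RPKM and Rps27 at 2253 and 2452 RPKM, and their direction reversed when values were rescaled to the germ cell list. No mitochondrially encoded gene was measured on its own.

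**Figure D3:**
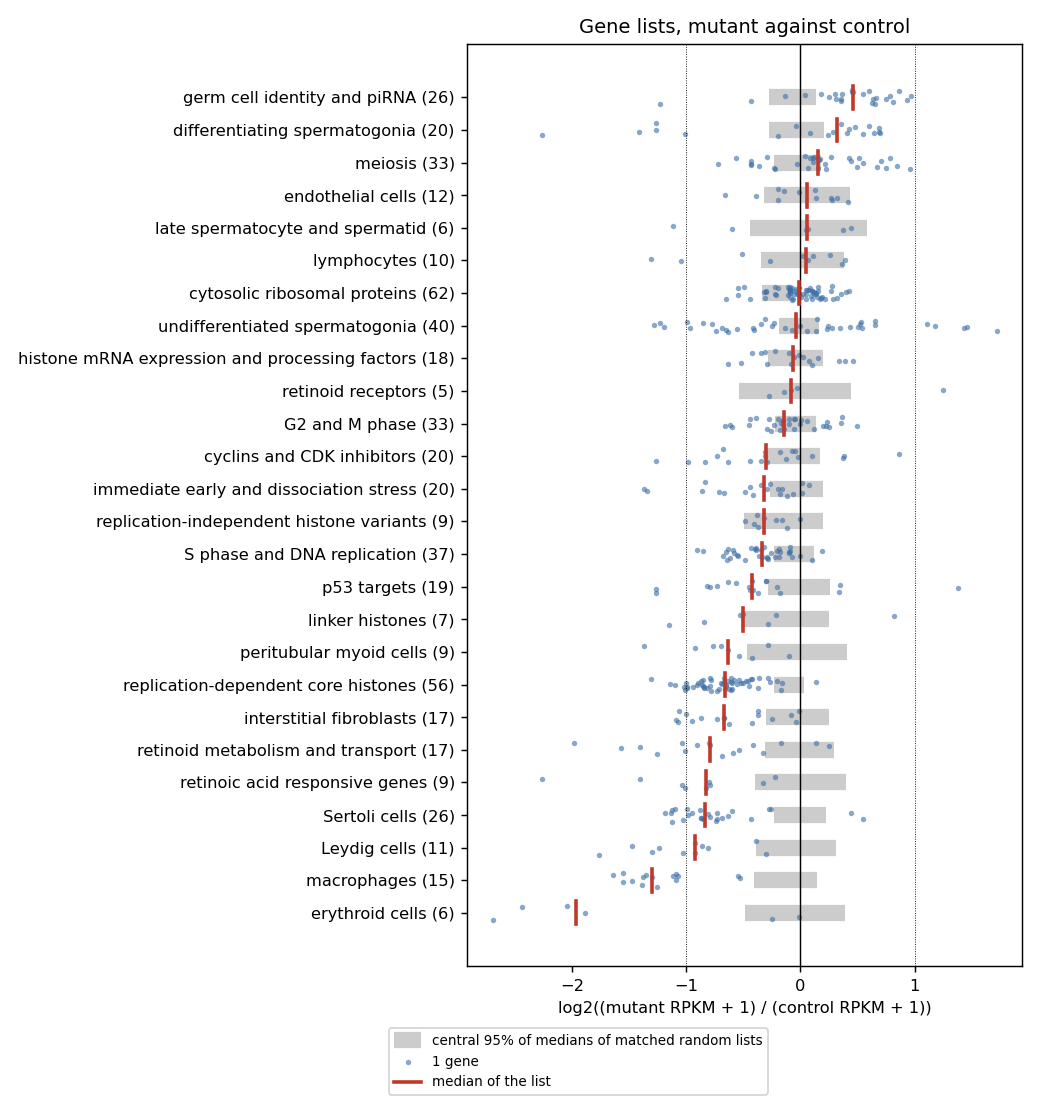
Log2 difference of mutant against control on the RPKM + 1 scale for every measured gene of 26 gene lists fixed in advance, with the number of genes in brackets. Points are genes, red bars are list medians, grey bands hold the central 95% of medians of 10000 random lists matched on expression, and dotted lines mark 2-fold. The germ cell identity median lies at 0.46 and becomes 0 by construction when values are rescaled to that list, which moves every other list down by the same step and turns the lists between 0 and 0.46 negative; macrophages lie at -1.30 and core histones at -0.66.

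Ranked by size alone, the largest differences came from 5S ribosomal RNA copies, which made up 9 of the 10 leading higher genes and 6 of the 10 leading lower ones. The remaining higher one was the small Cajal body RNA SCARNA4, which like those 9 was listed at 0 in control, and the remaining lower ones were Tpm3-rs7, Mcpt2, Cma1 and Tpsb2. Such copies are near-identical, so their reads can be assigned to one or another, and no fold is given for those listed at 0 in a genotype. They are also very short, so a few reads can make a large RPKM. For example, n-R5s54 and n-R5s164, both annotated at 112 nt, had the same mutant value of 23.5 RPKM. The protein-coding genes with the largest differences were therefore also ranked, together with named genes that had no symbol match in the annotation (Epb4.1l4a among those below), a choice made after the values were seen. The higher ones were led by Lemd1, a LEM domain gene (1.12 and 9.48 RPKM), the titin gene Ttn (7.25 RPKM in control and 4.41-fold higher in the mutant), Epb4.1l4a (1.80 and 9.62 RPKM), Hmgn5, a nucleosome-binding protein (2.49 and 12.2 RPKM), and Pde4c, a cAMP phosphodiesterase (6.49 and 26.9 RPKM). They went on with the ubiquitin ligase gene Fbxo32 (4.52 and 18.8 RPKM), Pxt1 (2.73 and 12.2 RPKM), Neurog3, Fgd5 (1.45 and 7.01 RPKM) and Spocd1, a factor of piRNA-directed DNA methylation (1.57 and 7.24 RPKM).

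The lower ones were led by Tpm3-rs7 (25.7 and 0.413 RPKM), a copy related to Tpm3 that can share its reads, which leaves this value uncertain, and by the mast cell protease genes Mcpt2 (65.9 and 3.42 RPKM), Cma1 (45.1 and 3.52 RPKM), Tpsb2 (46.9 and 4.36 RPKM) and Mcpt4 (32.7 and 3.20 RPKM). The haemoglobin genes Hbb-bs and Hba-a1 (122 and 21.7 RPKM), the chemokine gene Ccl24 (69.8 and 10.9 RPKM), the mast cell carboxypeptidase gene Cpa3 (25.5 and 3.66 RPKM) and C1qtnf6 (12.4 and 1.55 RPKM) completed them.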

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

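The settings that rescaled to the germ cell list, kept protein-coding genes alone, included entries with several symbols or removed the length and GC trend were chosen only after the result was seen; the other settings were planned. Across 138 results and 1340 alternative values, 1264 stayed within 1.5 times (of the fold for genes and lists, 0.58 on the log2 scale, so that a small log2 median can shift by much of its own size) without a change of sign (the germ cell list, set to 0 by its own rescaling, is among them), and 46 moved further without one. The sign changed in 4 for results past the 2-fold rule or outside the central 95% of random lists as reported, and in 26 for results short of these. Of them, 1 and 13 came from rescaling to the germ cell list, which moves all genes by the same step and leaves the order of lists as it was. That step of 0.46 is under the tolerance of 0.58, so no gene or list could move further under it. Settings that change only which entries are compared do not rescale the value of a single gene. Part of the total of 1264 was thus fixed in advance, and it is no measure of stability.

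The count of genes higher in the mutant, 729 as reported, was 1424 with a pseudocount of 0.1, 417 after rescaling to the germ cell list, 162 among protein-coding genes and 220 with the length and GC trend removed. The count of lower genes, 718 as reported, was 1111, 2503, 495 and 312 in turn. A smaller pseudocount raises the log2 difference of low genes by construction. Fewer genes were compared among protein-coding genes (12205 instead of 16504), which the trend removal also used. That alone does not account for the fall from 729 to 162 higher genes, because most higher genes were entries not matched as protein-coding. It does not account either for the counts of 220 and 312 on the same 12205 genes. Higher genes were 50.4% of all genes past the rule as reported, 14.3% after rescaling to the germ cell list, which lowers the median of all genes to -0.45, and 24.7% among protein-coding genes. The differentiating spermatogonia median reversed to -0.14 under that rescaling, a shift equal for all genes. The ribosomal protein median, near 0, reversed to 0.12 with quantile normalization, 0.0092 with entries of several symbols and 0.24 with the trend removed, and the cause was not tested. The retinoic acid responsive median ranged from -1.28 to -0.33 and the core histone median from -1.12 to -0.32 over the alternatives, negative in each. Counts of list members past the 2-fold rule moved as well. After rescaling to the germ cell list, lower members were 11 instead of 6 for retinoid metabolism (9 with a pseudocount of 0.1), 11 instead of 0 for S phase, 3 instead of 0 for G2 and M phase, 6 instead of 1 for cyclins, 7 instead of 2 for p53 targets (with 0 instead of 1 higher), 5 instead of 1 for myoid cells and 6 instead of 2 for immediate early genes, and higher early progenitor genes were 2 instead of 6. With the trend removed, 1 immediate early gene and 1 p53 target were lower, and 2 differentiating and 2 germ cell genes were higher. The erythroid median was -0.30 over 9 genes without the filter, and the mast cell median was -2.76 with a pseudocount of 0.1 and over the 8 genes with an RPKM of 5 or more.

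No paired analysis was possible because the columns carry no replicate values. For the same reason the planned variants of the linear model, the fits without 1 replicate, the gene set tests with other correlations, the count tests and the condition of non-overlapping replicates were not run. Depth limits genes near an RPKM of 0.03 in a 2-kb transcript, where a value rests on about 3 reads. The same reads make a higher RPKM in a shorter transcript, and the read step was not fitted below 1000 nt. The spread between replicates was not measured.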

Other observations

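The tests of length and GC content were planned, as were the pseudocount and RPKM settings and most gene lists. The other tests, the settings that rescale to the germ cell list or remove the length and GC trend, and the lists for mast cells, early progenitors, stem cells, DNA methylation and Y-linked genes were chosen only after the result was seen.

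Mast cell genes were lower in the mutant for 13 of 14 measured members, 10 of them by 2-fold or more, with a median log2 difference of -1.15. The median was -2.76 with a pseudocount of 0.1 and also over the 8 members with an RPKM of 5 or more, all of them past the 2-fold rule. Apoe, a lipoprotein gene abundant in macrophages and Leydig cells, was at 4557 RPKM in control and 1538 RPKM in mutant, and the beta-actin gene Actb at 5903 and 3176 RPKM. The early progenitor associated list was higher for 8 of 9 members, 6 by 2-fold or more, with a median of 1.18 and led by Neurog3, Sox3, Upp1 and Rarg, but it was drawn up with these values in view. The stem cell associated list had a median of -0.22 at percentile 6.87, inside the central 95% of random lists, with 4 of 12 members above 0. Gfra1 was its 1 member past the 2-fold rule. Lower members past 2-fold were 3 with a pseudocount of 0.1 or 0.5, 2 with quantile normalization and 5 after rescaling to the germ cell list.

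Of 13 genes of DNA methylation and chromatin of prospermatogonia, Dnmt3l, the cofactor of de novo DNA methylation, met the 2-fold rule (0.738 RPKM in control and 4.19 RPKM in mutant). The list median was 0.26 at percentile 97.49 (91.2 when matched on length and 99.5 when matched on GC content) and turned to -0.20 after rescaling to the germ cell list. The testis linker histone gene Hist1h1t was higher in the mutant (18.7 and 33.9 RPKM). The value that holds Xist together with other symbols was 7.45 RPKM in control and 0.683 RPKM in mutant, while the 6 Y-linked genes had a median of 0.34 that turned to -0.12 after the same rescaling, with Eif2s3y at 49.0 and 66.5 RPKM.

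Macrophage, mast, Leydig and Sertoli cell genes were lower in the mutant values. A lower share of every cell type other than germ cells alike was argued against by the endothelial median, which lay 1.36 above the macrophage median (95% bootstrap interval 0.95 to 1.62). A scaling difference between the values as the whole cause was argued against by ribosomal protein genes, whose median lay 1.29 above that of macrophages (1.05 to 1.45). A step common to all genes leaves this gap as it is, so the gap cannot show whether such a step is also present. How much of each somatic cell type the bead selection kept was not measured. A candidate explanation is that the preparations differed in particular somatic cells, whereas a response of the somatic testis to the germ cell genotype stays open. These cannot be told apart, because with 1 combined value per genotype the genotype and the cell preparation differ together.

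Core histone genes were lower by a median of -0.66. GC content alone was argued against as the whole cause by random lists matched on it, whose 2.5th percentile was -0.29. Length-matched lists had a 2.5th percentile of -0.44 and a median of -0.31, so length may account for a part. Whether length is the whole cause cannot be decided from them, because the match was made in bins. Many core histone genes, such as Hist1h2bh (chromosome 13, 23542970 to 23543357), are far shorter than 996 nt. That was the median length of the shortest decile of protein-coding genes, so the matched genes can be mostly longer. No list was matched on both properties. Fewer cells in S phase could lower these genes too: the histone median lay below the S phase median by a difference of -0.32 (-0.47 to -0.22), but by -0.03 (-0.21 to 0.11) with the length and GC trend removed. These readings cannot be told apart here, since the answer turns on that correction. Markers of interstitial fibroblasts (median -0.67) and Sertoli cells (-0.83) were lower in the same values, while endothelial genes had a median of 0.06. Whether a smaller share of somatic cell RNA lowered the histone and S phase genes was not tested and cannot be told apart here. A direct effect of the genotype on histone transcripts stays open and was not tested.

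Stra8 and Kit were lower in the mutant. A lower share of germ cells was argued against by the germ cell identity median of 0.46 (0.33 to 0.64), a list that a higher share of germ cell RNA could raise with no change per cell. Mast cells carry Kit, and their genes had a median of -1.15 (-2.83 to -0.79), or -2.76 with a pseudocount of 0.1, so a loss of mast cells may account for a part of the Kit difference. How much cannot be told apart from a loss in germ cells, because the Kit level of mast cells or any other somatic cell is in no table. Mast cells were the only somatic source of Kit considered, while Leydig cell genes, for example, were lower too (median -0.93). Impaired retinoic acid signalling, which the labels name, stays open as a hypothesis for both genes and has no replicate check here.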
